A study of Mus musculus and Rattus norvegicus with 24 samples.

How the data were processed

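Single cardiomyocytes were sorted by flow cytometry or picked by hand, and the labels do not say which cell was taken how. Their RNA was copied into cDNA with a template-switching reverse transcriptase, amplified, cut with Tn5 and sequenced over the length of transcripts, per the labels' protocols. The primers carried no stated molecular identifiers, so counts are reads and not molecules. The deposited values are whole-number counts per gene and cell. TopHat2 version 2.1.0, HTSeq and DESeq2, and the mouse build mm10, are named per the submitters' processing notes, for the rat cells too. Which tool made the counts, the annotation, the strand setting and the rule that chose the 9595 listed genes are not given in the sources used here. Of those genes, 692 had no count in any of the 24 cells. Mitochondrially encoded genes, the reporter genes and erythrocyte markers were not analysed here. Totals are of the listed genes, so they may be below the full library depth. Reads shared between close paralogs, such as the actins and myosins, and between overlapping or antisense genes, may be placed on either gene. Gene positions and union exon lengths came from GENCODE M21, on the same build, and 9322 symbols matched directly and 180 by an older name, 99.0% of all.

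Groups followed the sample titles: 8 transplanted, 8 cultured and 8 adult cells, with letters that only name cells. The labels name no animal or culture, so each group counted as 1 sample and gave no test, p-value or standard error. No pair of cells of a group agreed within sampling noise, since the chi-square per degree of freedom between 2 cells was at least 13.6. For each group the counts were summed over cells and divided by the group's total. A CPM carries an exact Poisson interval, a ratio of 2 groups an exact conditional binomial interval, and a share of counts an exact Clopper-Pearson interval, all at 95% and for counting error only. Against a group with 0 counts, the ratio was taken to a floor of 3 counts over the group and is a lower bound. The floor was 2.30 CPM in transplanted, 14.6 CPM in cultured and 2.36 CPM in adult cells. No ratio is given when both groups were at or under 3 counts.

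Gene lists, settings and most alternatives were fixed before the data were examined. They hold 25 lists, which cover the sarcomere, immature isoforms, excitation-contraction coupling, fatty acid oxidation, oxidative phosphorylation, TCA cycle, glycolysis, cell cycle, cardiac transcription factors, fetal growth, costamere and basement membrane, immediate early and heat shock, interferon response and hypoxia. The others are ribosomal proteins, mitochondrially encoded genes, markers of pluripotent, atrial, ventricular, fibroblast, endothelial, smooth muscle and pericyte, macrophage and leukocyte and erythrocyte cells, and a set of switch genes. A list's value is the median log2 ratio, with a pseudocount of 1 CPM, of members with at least 10 counts over both groups. Its percentile is among 10000 random lists of the same size matched on mean expression in 20 classes. A further percentile matched exon length in 5 classes too, but expression in only 5, so it is not a stricter form of the first. Both describe these libraries. Named genes follow a rule of size: per comparison, the 12 highest and 12 lowest log2 ratios among genes of at least 50 CPM, with counts in at least 6 of 8 cells of the higher group and at least a 2-fold ratio the same way with equal cell weights. Ribosomal protein, Gm-numbered and Rik-named genes were left out of that ranking. The rule adds the 3 members of each list with the highest CPM over both groups, and every switch gene. Some of them are not reported here, and the check for cells that stand apart leaves those out. The text prints a part of these genes and says where another was chosen after its values were seen.

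Profiles were compared by Spearman's rho of log2(CPM + 1). Genes per cell were counted after thinning to 100154 counts, the shallowest cell with at least 100000. No cultured cell reached that depth, so 16099 counts, the shallowest of all cells, was added after the totals were seen and serves the cultured group. Also added then were a protein-coding denominator, lists matched on exon length, a minimum of 5 counts at this depth, and leaving out each cell for the named ratios, the other lists and the shares. Ratios over subsets of cultured cells chosen by their measured profiles or cardiac counts were also computed and then left out, because cells chosen by an outcome cannot stand as a group. Over cultured cells A, F, G and H alone, Myh6, Myh7, Ryr2, Ttn and the immature isoform list (adult against cultured) had turned direction. Cells F, G and H had no count of Myh6, Myh7, Ryr2 or Ttn, so for these genes that outcome largely followed from the choice of cells.

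Alternatives were TMM factors of edgeR 4.0.16 and median-of-ratios size factors of DESeq2 1.42.0, on the group sums and with no model fitted, equal cell weights, other minimums and pseudocounts, common depths and leaving out each cell. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3. The steps were tested on simulated data over 9595 genes, drawn from the real means with changes planted. For transplanted against cultured cells, a planted log2 ratio of 1 was recovered at a median of 0.853 with the right sign in 80% of genes, and one of 3 at 2.94. Recovered ratios and signs were scored after taking out the shift in totals known from the planted changes. The real ratios have no such correction. Lists with no planted change lay at percentiles 78.7, 94.4 and 24.2 in the 3 comparisons. The simulated cells varied less than the real ones, and a recovered median was accepted within 0.8 on the log2 scale, so the test shows that the arithmetic works and not how precise the real ratios are.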

Results

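Single cells, given as cardiomyocytes by the labels, were profiled by RNA sequencing in 3 groups of 8 cells, 24 cells in all. Transplanted cells were made from mouse embryonic stem cells and kept for 30 days in a neonatal rat heart. Cultured cells came from the same stem cell line, which carries Isl1-Cre, Rosa-RFP and aMHC-GFP reporters, and spent those 30 days in a dish. Adult cells were isolated as ventricular cardiomyocytes from adult rats. Total counts ran from 88796 to 344224 in the transplanted cells, from 16099 to 60789 in the cultured cells and from 108546 to 223744 in the adult cells. The labels name no animal or culture, so each group was 1 sample, no test between groups was possible, and cells were not used as replicates. Levels (CPM) are counts of the sum over 8 cells scaled to a total of 1000000, ratios are between those sums, and brackets hold exact 95% intervals. Where leaving out 1 cell moved a ratio by over 1.5 times, or made or ended a bound, the brackets also give the ratio without that cell, a setting added after the data were seen. Shares of counts are treated likewise. List medians carry their lowest and highest value without 1 cell and, where it differs by over 1.5 times, the value with genes at 0 set to the floor. Intervals and floors cover counting error only, since reads from PCR are not independent molecules.

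Signs of library quality differed between the groups. Rn45s, the ribosomal RNA precursor, is outside the rule for named genes and was chosen after its values were seen. It took a median of 7.02% of counts per cultured cell (1.29 to 13.2%). The medians were 1.20% per transplanted cell (0.547 to 1.78%) and 1.23% per adult cell (0.748 to 1.95%). Cultured cells A and F, at 1.84% and 1.29%, lay within the adult range. The count-weighted median exon length without Ttn was 3738 to 6983 bp in cultured cells, 1950 to 2284 bp in transplanted cells and 2044 to 2352 bp in adult cells. A percentile is therefore also given against random lists matched on exon length, an addition made after these lengths had been seen. At 16099 counts per cell, a median of 1458.5 genes was detected per cultured cell (716 to 2451), 599 per transplanted cell (454 to 1034) and 686.5 per adult cell (502 to 1234). With at least 5 counts at that depth, added for transplanted and adult cells after the data were seen, the medians were 762.5, 417.5 and 430.5. At 100154 counts, which no cultured cell reached, the medians were 817 in 7 transplanted cells and 868.5 in 8 adult cells. As deposited, they were 1494, 754 and 930 in cultured, transplanted and adult cells.

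Cultured cells differed widely from one another. In cells A to H the share of Rpph1, the RNA of RNase P, was 0.0202%, 4.96%, 2.51%, 5.48%, 5.30%, 0.0541%, 0.0574% and 0.0293%, and the count-weighted median exon length was 3783, 6983, 6553, 6785, 6780, 4994, 3738 and 4221 bp. Actc1, cardiac actin, had 112, 22, 47, 0, 4, 1, 0 and 0 counts and Tnnt2, cardiac troponin T, 14, 0, 2, 22, 0, 0, 0 and 0. Cells G and H had no count of Ttn, Myh6, Tnnt2, Actc1 or Tpm1, and 20 and 1 of Myl7. Cell F had none of Ttn, Myh6 or Tnnt2, 1 of Actc1, 58 of Tpm1 and 78 of Myl7. By these genes, that cell H was a cardiomyocyte rests on the label. For cells F and G it rests on the label and mainly on Myl7, at 4222 and 883 CPM. Markers of other cell types took 0.101%, 0.137%, 0.139%, 0.0108%, 0.0248%, 0.189%, 0% and 0.209% of counts in cells A to H.

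The first comparison set transplanted against cultured cells and asked how 30 days in the heart, in place of a dish, went with the state of stem cell-derived cardiomyocytes. Most measured ventricular genes (5 of 6) and sarcomere genes (15 of 21) were higher in transplanted cells. Myl2, the ventricular regulatory light chain, stood at 42473 CPM (42120 to 42828.5) in 8 of 8 cells against 437 CPM (351 to 537) in 1 of 8 cultured cells, 97.3-fold higher (79.1 to 121, at least 2639 without cultured A). Tnni3, the adult cardiac troponin I, was 309-fold higher (208 to 482, at least 2235 without cultured A), and Tpm1, a tropomyosin, 40.3-fold higher (34.9 to 46.7). Tnni1, the slow skeletal troponin I of the fetal heart, had 329.8 CPM (256 to 418) in 5 cultured cells and no count in transplanted cells, so it was at least 143-fold lower (at least 88.6 without cultured A). Myl7, the atrial light chain, was at least 697-fold lower (at least 308 without cultured A), from 1605 CPM (1437 to 1788) in 7 of 8 cultured cells to 0 counts. Cox7a1, a muscle subunit of cytochrome oxidase, had no count in cultured cells and 11155 CPM (10975 to 11338) in 8 of 8 transplanted cells, at least 767-fold higher.

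Of the sarcomere list, 15 of 21 measured genes were higher in transplanted cells, with a median log2 ratio of 4.64 (percentile 99.97 of random lists, 100 with exon length matched, and 4.16 without cultured B to 5.50 without cultured A). The list took 20.6% (20.5 to 20.7) of counts in transplanted and 5.23% (5.14 to 5.33) in cultured cells. Most of the cultured share was Ttn: without it the list had 0.722% (0.686 to 0.759) of cultured and 20.4% (20.3 to 20.5) of transplanted counts. With Ttn, the share in cultured cells A to H was 1.84%, 4.78%, 17.0%, 11.8%, 8.35%, 0.379%, 0% and 0.00419%. Myl3, a ventricular light chain, was 334-fold higher (214 to 555, 574 without cultured A) and Actc1 24.9-fold higher (21.6 to 29.0, 56.6 without cultured A). Myoz2, a Z-disc protein, was at least 245-fold higher. Ttn, the giant spring protein titin, went the other way, with 2131 CPM (2053 to 2212) against 45111.5 CPM (44199 to 46038), 21.2-fold lower (20.3 to 22.1). Its cultured counts were uneven, at 14, 2685, 2499, 2849, 1254, 0, 0 and 0 in cells A to H. That direction thus rested on cells B to E, the libraries with the highest Rpph1 shares and the longest exons. Myh6, the alpha myosin heavy chain whose promoter drives the GFP reporter, was 2.47-fold lower (2.23 to 2.72, 1.31 without cultured D). It had 3, 73, 175, 300, 5, 0, 0 and 0 counts in cultured cells A to H and counts in 8 of 8 transplanted cells, so this direction of the sums did not hold for every cell.

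The immature isoform list had 6 of 9 measured genes lower in transplanted cells, a median of -5.89 (percentile 6.5, 1.72 with length matched, -6.84 without transplanted E to -5.77 without cultured A). That median was close to the -5.63 of all measured genes. Random lists matched on expression had a median of -1.75 (0.139 with length matched). Myh7, the beta myosin heavy chain, was 47.1-fold lower (31.9 to 72.0, 129 without transplanted E and 23.7 without cultured C), with counts in 4 cultured and 5 transplanted cells. Its cultured counts all lay in the same libraries, B to E, at 0, 19, 116, 39, 42, 0, 0 and 0 in cells A to H. The share of the list there was 1.49%, 0.168%, 1.01%, 0.212%, 0.429%, 0.476%, 0.0927% and 0.00419%, against 0.00959 to 0.185% in transplanted cells. Acta2, smooth muscle actin, was 803-fold lower (141 to 31945, at least 238 without transplanted A and 484 without cultured B). Nppb, a natriuretic peptide gene of stretched muscle, went against the list, at 517 CPM (478 to 557) in 4 transplanted cells and 0 counts in cultured cells, at least 35.5-fold higher (at least 22.8 without transplanted H). Acta1, skeletal actin, had 9.98 CPM (5.31 to 17.1, 2.49 without transplanted G) in transplanted cells, below the 14.6 CPM that 0 cultured counts allow. Nppa had no count in any of the 24 cells.

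Oxidative phosphorylation genes were higher in 23 of 24 cases, with a median of 4.34 (percentile 99.62, 99.89 with length matched, 4.13 without cultured D to 5.15 without cultured A), and took 13.1% (13.1 to 13.2) of transplanted against 0.607% (0.574 to 0.641) of cultured counts. Single cells had 11.8 to 14.6% and 0.0717 to 1.92%. Slc25a4, the mitochondrial ADP/ATP carrier of muscle, was 61.8-fold higher (49.3 to 78.6, 106 without cultured G) and Cox6a2 90.8-fold higher (62.8 to 137, 177 without cultured A and 138 without cultured C). Cox4i1 was 51.8-fold higher (38.9 to 70.5, 88.0 without cultured A and 98.4 without cultured G). Fatty acid oxidation genes were higher in 18 of 21 cases, median 4.15 (percentile 99.87, 100 with length matched, 3.96 without cultured D to 5.52 without cultured B). Fabp3, the heart fatty acid binding protein, was 1481-fold higher (266 to 58505, at least 436 without cultured H), Etfb 17.8-fold higher (13.7 to 23.4, 26.6 without cultured G) and Cd36, a fatty acid transporter, at least 68.0-fold higher (at least 29.2 without transplanted D). Cpt1b, the muscle carnitine palmitoyltransferase, had 1 count in all transplanted cells and none in cultured cells. The TCA cycle list had a median of 3.08 with 14 of 16 genes higher (percentile 98.48, 2.70 without transplanted E to 4.08 without cultured B), and glycolysis 1.26 with 10 of 16 (percentile 94.11, 0.75 without transplanted H to 1.39 without transplanted D). Aldoa was 6.33-fold higher (5.56 to 7.24, 11.9 without cultured F).

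Excitation-contraction coupling genes were higher in 10 of 14 cases, median 3.01 (percentile 99.33, 99.85 with length matched, 2.32 without transplanted B to 3.45 without transplanted H, and 0.00 with no count minimum). Pln, the inhibitor of the calcium pump, was 61.2-fold higher (39.1 to 102, 525 without cultured A) and Atp2a2, the pump itself, 6.92-fold higher (5.47 to 8.88, 10.6 without cultured A). Ryr2, the calcium release channel, was 4.90-fold lower (4.04 to 5.94), with counts in 5 cultured and 6 transplanted cells. Its cultured counts were 9, 42, 51, 24, 68, 0, 0 and 0 in cells A to H, so that direction rested on cells B to E, the libraries with the highest Rpph1 shares and the longest exons.

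Cell cycle genes were lower in 11 of 12 cases, median -6.05 (percentile 7.34, 9.47 with length matched, -6.54 without cultured B to -5.96 without cultured F, -4.82 with zeros at the floor), with 0.199% (0.180 to 0.219) of cultured and 0.00721% (0.00583 to 0.00883, 0.00425 without transplanted E) of transplanted counts. The median of all measured genes was -5.63, and random lists matched on expression had a median of -5.70 (-5.40 with length matched). The cell cycle median lay only slightly below these values, so it does not show a fall specific to this list. In cultured cells A to H the cell cycle share was 0.111%, 0.0115%, 0.0422%, 0%, 0.776%, 0.855%, 0.402% and 0%. Most of it lay in cells E, F and G, whose sarcomere shares were 8.35%, 0.379% and 0%. Top2a, a topoisomerase of dividing cells, had 393 CPM (312 to 488) in 2 cultured cells and was at least 171-fold lower (at least 15.99 without cultured E).

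Among the genes ranked by size, Mb, myoglobin, stood at 24276 CPM (24009.6 to 24545) and was 2503-fold higher (693 to 20666, at least 1508 without cultured A). Ckm and Ckmt2, the muscle creatine kinases, were at least 357-fold higher and at least 244-fold higher. On the other side Rpph1 was at least 12320.2-fold lower, H19, an imprinted growth regulator, at least 1173-fold lower (at least 617 without cultured H) and Eef1a1, an elongation factor, at least 1007-fold lower. H19 had 84, 2, 1, 13, 4, 5, 150 and 298 counts in cultured cells A to H. In mm10, Cox7a1 lies on chromosome 7, 30184144 to 30186078, Myl2 on chromosome 5, 122100951 to 122113472 and H19 on chromosome 7, 142575529 to 142578143. Markers of other cell types took small shares of the group sums, but many were not among the listed genes. Present were 8 of 11 fibroblast, 4 of 7 smooth muscle and pericyte, 3 of 10 macrophage and leukocyte and 5 of 10 endothelial genes. In cultured cells A to H the fibroblast share was 0.0959%, 0.0855%, 0.109%, 0%, 0%, 0.189%, 0% and 0.209%. Among those with fibroblast counts, the sarcomere share was 1.84%, 4.78%, 17.0%, 0.379% and 0.00419% in cells A, B, C, F and H. The fibroblast list had 0.0844% (0.0723 to 0.0979) in cultured and 7.68e-05% (1.94e-06 to 0.000428, 0 without transplanted E) in transplanted cells, and smooth muscle and pericyte 0.0107% (0.00669 to 0.0162) and 0.000384% (0.000125 to 0.000896, 8.61e-05 without transplanted A). Macrophage and leukocyte markers had 0.0102% (0.00631 to 0.0156, 0 without cultured B) and 0% (0 to 0.000283), and endothelial markers 0.000485% (1.23e-05 to 0.00270, 0 without cultured A) and 0.0167% (0.0146 to 0.0191, 0.0106 without transplanted D and 0.00898 without transplanted G). The median log2 ratio of all 4958 measured genes was -5.63, and TMM factors shifted every ratio by 0.92. The groups had different depths, so an absent count in cultured cells bounds a level less tightly than one in transplanted cells.

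**Figure D1:**
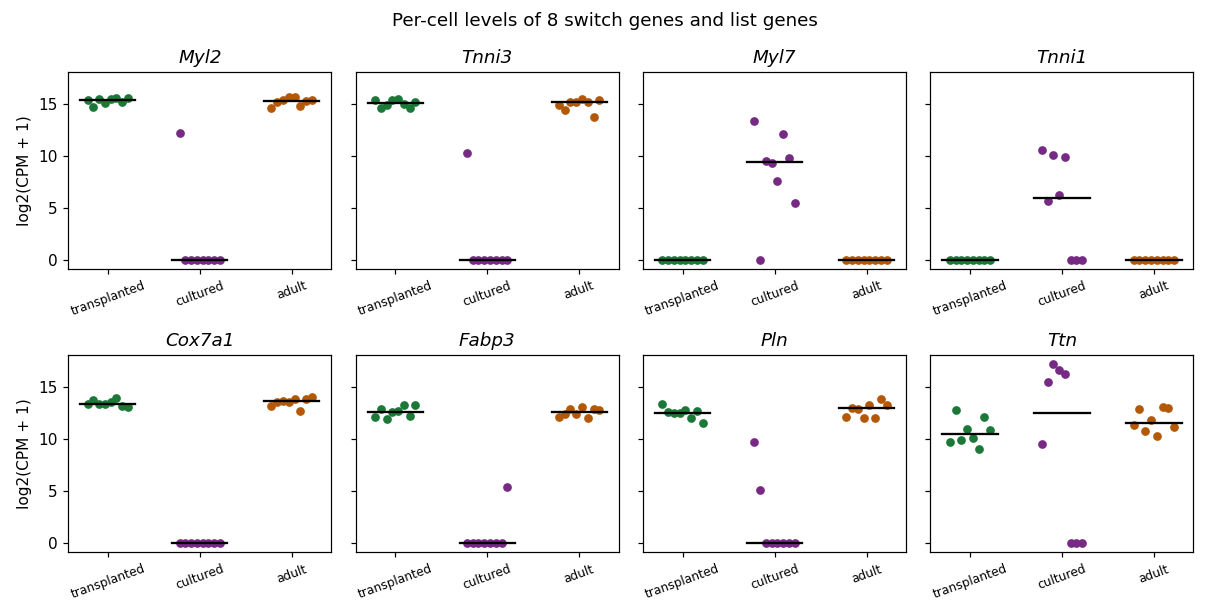
Each point is 1 cell, 8 per group, at log2(CPM + 1) of 8 genes, and the bar is the group's median. Myl2 and Tnni3 had counts in 1 of 8 cultured cells and in 8 of 8 cells of both other groups, while Myl7 had counts in 7 cultured cells and in 0 others.

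The second comparison set adult rat cells against the cultured cells, as the mature reference, and it shares its cultured cells with the first. Adult cells had 38705 CPM (38364 to 39049) of Myl2 in 8 of 8 cells, 88.7-fold higher (72.1 to 110.3, at least 2404 without cultured A), and 32558.5 CPM (32246 to 32874) of Tnni3, 279.7-fold higher (188 to 437, at least 2023 without cultured A). Tnni1 and Myl7 had no adult counts and were at least 139.8-fold lower (at least 86.4 without cultured A) and at least 680.4-fold lower (at least 300.2 without cultured A). Cox7a1 was at least 866-fold higher and Mb 2960.3-fold higher (819 to 24445, at least 1784 without cultured A).

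Sarcomere genes were higher in 16 of 21 cases (median 4.75, percentile 99.98, 100 with length matched, 4.25 without cultured B to 5.54 without cultured A). Oxidative phosphorylation genes were higher in 24 of 24 (median 4.28, percentile 99.93, 99.86, 3.83 without cultured B to 5.22 without cultured A), and fatty acid oxidation genes in 21 of 23 (median 3.85, percentile 99.89, 99.95, 3.71 without adult A to 4.71 without cultured E). Excitation-contraction coupling genes were higher in 16 of 20 cases, median 2.56 (percentile 98.14, 99.98 with length matched, 2.20 without adult B to 2.98 without cultured C). Slc25a4 was 55.6-fold higher (44.3 to 70.7, 95.1 without cultured G) and Fabp3 1293-fold higher (232 to 51089, at least 381 without cultured H). Pln was 85.9-fold higher (55.0 to 143, 738 without cultured A) and Casq2, calsequestrin, at least 29.0-fold higher (at least 16.4 without adult F). Cell cycle genes were lower in 11 of 11 cases, median -6.20 (percentile 0.67, 3.48 with length matched, -6.79 without cultured B to -6.05 without cultured G, -4.95 with zeros at the floor). For that list, random lists matched on expression had a median of -5.63 (-4.25 with length matched), and all measured genes had -3.85. The immature isoform list was mixed, with 6 of 9 genes lower and a median of -3.09 (percentile 32.86, 10.38 with length matched, -5.86 without adult D to -1.80 without cultured F). Acta1 stood at 899 CPM (848 to 953) in 7 adult cells, at least 61.8-fold higher (at least 38.5 without adult C). Nppb was at least 29.9-fold higher (at least 18.5 without adult E), while Myh7 was 8.59-fold lower (6.96 to 10.6, 61.6 without adult D and 4.33 without cultured C). The immature isoform median turned to 4.27 with members of at least 100 counts alone. Ttn was 11.1-fold lower (10.7 to 11.5) and Myh6 1.84-fold lower (1.67 to 2.02, 1.02-fold higher without cultured D); the log2 ratio of Myh6 was 0.0412 with TMM factors. The lower cell cycle, immature isoform, Ttn, Myh6 and Myh7 values here rest on the same uneven cultured cells as in the first comparison.

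Eno3, the muscle enolase, was at least 217-fold higher, Ckm at least 359-fold higher and Ak1, an adenylate kinase, at least 77.9-fold higher (at least 49.5 without adult F). H19 was at least 1145-fold lower (at least 602 without cultured H), Ywhab, a 14-3-3 protein, at least 623-fold lower (at least 181 without cultured D) and Map1b, a microtubule protein, at least 475-fold lower. The TCA cycle median was 3.09 (percentile 98.97, 2.56 without adult D to 4.13 without cultured B) and the glycolysis median 1.78 (percentile 97.47, 1.18 without adult G to 1.98 without cultured F). Species differed along with the group here, rat against mouse, and the submitters' processing notes list only a mouse build, so a rat-to-mouse difference in alignment could not be separated from a difference between the cells. TMM factors shifted every ratio by 0.92 from a median of -3.85 over 5132 genes.

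The third comparison set adult against transplanted cells directly, without the cultured cells. The sarcomere, fatty acid oxidation and oxidative phosphorylation medians lay near 0, with members going both ways: sarcomere 0.11 (11 of 20 genes higher in adult cells, percentile 77.77, -0.00709 to 0.18 without 1 cell), fatty acid oxidation 0.0382 (13 of 24, percentile 51.96, -0.18 to 0.29) and oxidative phosphorylation -0.0546 (12 of 24, percentile 44, -0.13 to 0.0296). Other lists had medians of 0.0485 for TCA cycle (16 measured, percentile 59.59, -0.15 to 0.25), 0.0213 for glycolysis (15 measured, percentile 49.46, -0.32 to 0.15), -0.13 for ventricular (5 measured, percentile 44.17, -0.20 to 0.11) and 0.29 for ribosomal proteins (60 measured, percentile 52.12, 0.23 to 0.52). Other lists lay further from 0. The cardiac transcription factor median was 3.95 (10 measured, percentile 87.52, 1.18 without adult G to 4.37 without transplanted B). The pluripotency median was 3.98 (2 measured, percentile 100, 3.29 without adult A to 4.15 without adult H, 3.35 with zeros at the floor). The atrial median was 3.27 (1 measured, percentile 70.72, 3.27 without transplanted A to 3.52 without adult A, 1.91 with zeros at the floor). Its 1 measured gene was Nr2f2, whose 11 adult counts all lay in adult D, so the median has no value without that cell. The endothelial median was -7.39 (1 measured, percentile 9.97, -7.75 without transplanted H to -6.50 without transplanted G, -6.14 with zeros at the floor). The costamere median was -2.92 (10 measured, percentile 2.91, -3.36 without transplanted H to 0.78 without transplanted B). The interferon response median was 1.79 (2 measured, percentile 62.79, -0.87 without adult C to 4.67 without transplanted A, 1.14 with zeros at the floor). The hypoxia response median was 0.51 (3 measured, percentile 51.97, -1.14 without adult D to 3.38 without transplanted A). The immediate early and heat shock median was 0.70 (6 measured, percentile 59.18, -1.09 without adult G to 3.92 without transplanted D). Tpm1 stood at 36226.5 CPM (35896 to 36559) in adult and 36509 CPM (36181 to 36838) in transplanted cells, and Cox6a2 at 12483 CPM (12289 to 12678) and 12337 CPM (12147 to 12529). Acta1 was 90.1-fold higher (52.5 to 169.7, 56.2 without adult C and 360.4 without transplanted G) in adult cells, with counts in 7 adult and 3 transplanted cells. Casq2, the calcium store protein, was 7.74-fold higher (6.03 to 10.1, 4.39 without adult F and 69.9 without transplanted A), in 7 adult and 2 transplanted cells.

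Excitation-contraction coupling genes were higher in adult cells in 14 of 20 cases, median 0.55 (percentile 74.42, 0.28 without adult H to 1.36 without transplanted D). Pln was 1.40-fold higher (1.36 to 1.45) and Atp2a2 stood at 3574 CPM (3471 to 3679.9, 2111 without adult H) against 2382 CPM (2299 to 2468), so its direction turned without that 1 cell. The immature isoform list had 5 measured genes, 4 of them higher in adult cells, with a median of 2.40 (percentile 98.15, 0.61 without adult D to 3.75 without transplanted E), which was 0.00 with no count minimum. Ankrd1, a stress-responsive sarcomere protein, was 2.76-fold higher (2.42 to 3.15, 1.53 without adult D and 7.77 without transplanted B). Acta2 was 682-fold higher (122 to 26994, 372 without adult A and at least 203 without transplanted A), with counts in 5 adult cells and 1 count in transplanted cells. Among cell cycle genes 3 were measured, with a median of -3.38 (percentile 18.39, -4.22 without adult H to -1.06 without transplanted E), and Pcna and Cenpf each had transplanted counts in 1 cell. That median turned to 0.82 with members of at least 100 counts and to 1.11 with only cells of 100000 counts and 1000 genes. Got2 and Sdha, both mitochondrial enzymes, were 95.8-fold higher (37.1 to 353, 56.1 without adult E and 347 without transplanted B) and 22.1-fold higher (17.3 to 28.9, 12.6 without adult G and 72.4 without transplanted B). Hk2, a hexokinase, was 19.6-fold higher (12.7 to 32.0, at least 127 without transplanted G). Acat1, a ketone body enzyme, was 8.61-fold lower (7.65 to 9.72, 31.5 without adult B) in adult cells. Idh2, of the mitochondrial matrix, was 3.96-fold lower (3.50 to 4.49), Hsp90ab1, a chaperone, 4.66-fold lower (4.25 to 5.12, 7.94 without adult E) and Ckmt2 1.56-fold lower (1.49 to 1.63, 2.37 without adult F). Fabp4, a marker of the endothelial list, had 167 CPM (145 to 190.3, 89.8 without transplanted G) in 3 transplanted cells and no adult count. Species again went with the group, so rat and mouse sequence could not be separated from host and origin.

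Across 3061 genes with at least 50 counts over 24 cells, Spearman's rho of the group profiles was 0.34 between transplanted and adult cells, -0.18 between cultured and adult cells and -0.20 between transplanted and cultured cells. Without cultured cell B the last 2 values were -0.0880 and -0.11. Genes are not independent replicates, so these values describe the profiles. Between single cells the median rho was 0.38 for transplanted and adult pairs, 0.38 within transplanted cells and 0.36 within adult cells. It was 0.11 within cultured cells, 0.0255 for cultured and adult pairs and 0.0216 for transplanted and cultured pairs. The 2 negative values of the sums depended on the count minimum: with no minimum they were 0.0409 and 0.0470, and that of transplanted and adult cells was 0.49.

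**Figure D2:**
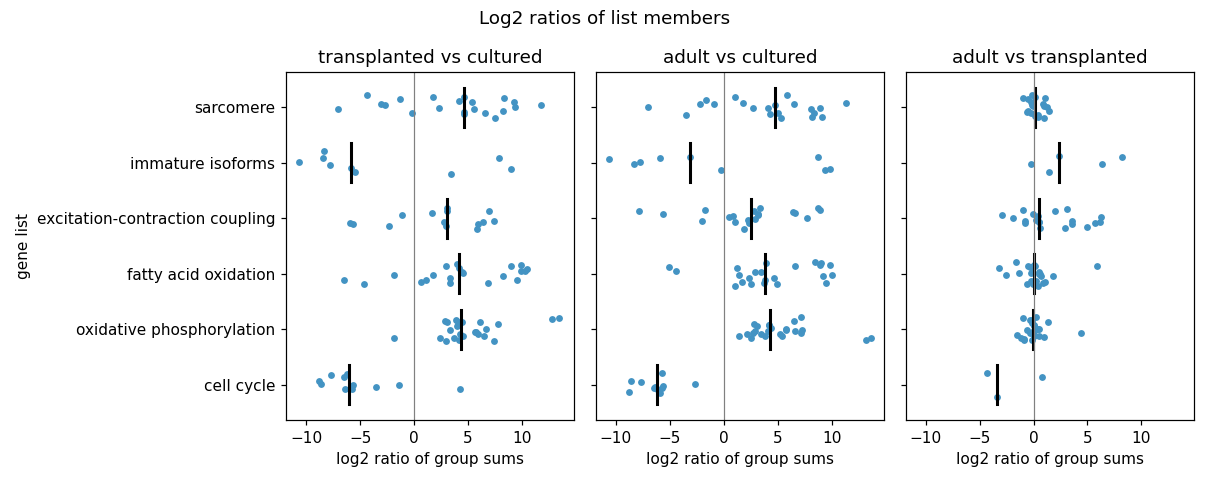
Each point is 1 measured list gene at its log2 ratio of group sums, and the bar is the list's median. The oxidative phosphorylation median was 4.34 for transplanted and 4.28 for adult against cultured cells, and -0.0546 between adult and transplanted cells.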

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

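Of 81 groups of 8 values, 10 held 1 cell whose gap to its nearest neighbour exceeded the 5% critical value of Dixon's ratio. In 7 of them this was fixed by construction, since 1 cell held every count of a gene. Of the other 74 groups, 3 held such a cell, where chance, at 1 in 20, would give about 3.70. Transplanted cell H had 344224 counts against a group median of 146660, and cultured cell B had 60789 against 21236. Transplanted cell H also had the lowest Myh6 level of its group, 7.59 on the log2(CPM + 1) scale used for the genes here.

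Where 1 cell held every count of a gene, the value only shows which cell that was. Cultured cell A was the 1 cultured cell with Myl2 (12.15, 90 counts) and with Tnni3 (10.24, 24 counts), so the cultured level of both genes rests on it. Nkx2-5, a cardiac transcription factor, had 5 counts in adult cell C (5.16). Cpt1b had 2 counts in adult cell G (3.66) and 1 in transplanted cell A (3.01), where Acta2 also had 1 (3.01). Fabp3 had 1 count in cultured cell H (5.42).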

How the results depend on the processing

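Tests at a depth of 16099 counts, with a protein-coding denominator and of named ratios and other lists without 1 cell were added after the data were seen. A value counted as moved when it changed by at least the SD of the same quantity over single cells, and as reversed when a median of at least 0.5 in size changed sign. Of 173 alternative list medians 147 stayed within that spread, and 3 reversed. In the 3 comparisons the sarcomere, fatty acid oxidation and oxidative phosphorylation medians stayed within it under every alternative run, though this spread was wide (2.20 for sarcomere, transplanted vs cultured). The cell cycle medians moved most often, and their spread over single cells was only 0.13 and 0.0923 against cultured cells. There, 9 of 12 measured members had no transplanted count and 10 of 11 no adult count. Zeros and the pseudocount therefore largely set these medians and kept their spread small. With a pseudocount of 0.1, the values were immature isoforms -9.19 (transplanted vs cultured), cell cycle -9.35 (transplanted vs cultured), -9.51 (adult vs cultured) and -4.32 (adult vs transplanted). With no count minimum, the values were excitation-contraction coupling 0.00 (transplanted vs cultured), cell cycle -5.38 (transplanted vs cultured), -5.70 (adult vs cultured) and 0.00 (adult vs transplanted), immature isoforms 0.00 (adult vs transplanted), rho of transplanted and adult 0.49, rho of cultured and adult 0.0409, rho of transplanted and cultured 0.0470. TMM factors gave cell cycle -5.44 (transplanted vs cultured) and -5.60 (adult vs cultured). Equal cell weights gave cell cycle -6.47 (transplanted vs cultured) and -6.56 (adult vs cultured). With a minimum of 100, the values were cell cycle -3.51 (transplanted vs cultured), -2.69 (adult vs cultured) and 0.82 (adult vs transplanted), immature isoforms 4.27 (adult vs cultured). With a pseudocount of 10, the values were cell cycle -3.13 (transplanted vs cultured), -3.05 (adult vs cultured) and -1.36 (adult vs transplanted). Thinning to 16099 counts gave cell cycle -6.56 (transplanted vs cultured) and -6.56 (adult vs cultured). A protein-coding denominator gave cell cycle -6.27 (transplanted vs cultured) and -6.43 (adult vs cultured). Size factors gave cell cycle -6.09 (adult vs cultured). Only cells of 100000 counts and 1000 genes gave cell cycle 1.11 (adult vs transplanted). With a minimum of 500, the values were rho of transplanted and adult 0.49, rho of cultured and adult 0.0872, rho of transplanted and cultured 0.0717. At 5 counts or more after thinning to 16099, the values were genes per cell, transplanted 417.5, genes per cell, adult 430.5. At 5 counts or more, the values were genes per cell, cultured 762.5. Leaving out 1 cell at a time gave cell cycle medians of -6.54 to -5.96 (transplanted vs cultured), -6.79 to -6.05 (adult vs cultured) and -4.22 to -1.06 (adult vs transplanted). Myh6 was 0.0412 with TMM factors (adult vs cultured). Without 1 cell, 63 of 87, 65 of 88 and 60 of 79 ratios of named genes moved by over 1.5 times or made or ended a bound, in the order transplanted vs cultured, adult vs cultured and adult vs transplanted. Without 1 cell, 13 named log2 ratios and 8 list medians of at least 0.5 in size changed sign, and so did 17 and 7 smaller ones, such as interferon response, adult vs cultured (-4.29 to 0.51). The ranges of the larger ones were -3.78 to 0.19 (pluripotency transplanted vs cultured), -5.96 to 0.42 (immediate early and heat shock transplanted vs cultured), -1.47 to 4.47 (pluripotency adult vs cultured), -3.03 to 0.17 (immediate early and heat shock adult vs cultured), -1.09 to 3.92 (immediate early and heat shock adult vs transplanted), -0.87 to 4.67 (interferon response adult vs transplanted), -1.14 to 3.38 (hypoxia response adult vs transplanted), -3.36 to 0.78 (costamere and basement membrane adult vs transplanted), -5.63 to 1.72 (Rgs5 transplanted vs cultured), -3.00 to 1.40 (Vegfa transplanted vs cultured), -5.63 to 1.75 (Rgs5 adult vs cultured), -2.07 to 2.62 (Jun adult vs cultured), -5.38 to 1.21 (Fos adult vs cultured), -0.58 to 1.91 (Vegfa adult vs cultured), -1.18 to 0.0292 (Myh6 adult vs cultured), -2.59 to 1.04 (Phb adult vs transplanted), -0.17 to 0.85 (Atp2a2 adult vs transplanted), -4.22 to 0.84 (Cenpf adult vs transplanted), -1.14 to 4.08 (Vegfa adult vs transplanted), -0.82 to 1.36 (Cpt1b adult vs transplanted) and -0.37 to 3.75 (Myh7 adult vs transplanted). The 13 log2 ratios were not held to the rule that gives no ratio when both groups are at or under 3 counts. By that rule Cpt1b, with 2 adult counts and 1 transplanted count, has no ratio. Rgs5 has none without cultured B, and Cenpf none without transplanted A, so these genes show no sign change of a ratio. With genes at 0 set to the floor, the medians for transplanted and adult against cultured cells were 4.64 and 4.48 for sarcomere, -5.56 and -3.10 for immature isoforms, 2.89 and 2.47 for excitation-contraction coupling, 4.15 and 3.45 for fatty acid oxidation, 4.25 and 4.17 for oxidative phosphorylation, and -4.82 and -4.95 for cell cycle. A denominator with mitochondrially encoded genes was not run, and the planned depth and the cell filter gave no cultured value. No paired analysis was possible because the letters only name cells and no test was made.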

Other observations

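Tests here were chosen after the data had been seen; for exon length and depth, only the outcomes that would count for or against them were written before their own values were computed.

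Imprinted and fetal growth genes were high in the cultured group, unevenly over its cells. The fetal growth list had 0.624% (0.590 to 0.659) of cultured, 0% (0 to 0.000283) of transplanted and 0.000157% (1.90e-05 to 0.000568, 0 without adult F) of adult counts, with median log2 ratios of -9.18 for transplanted and -8.79 for adult against cultured cells. Without 1 cell these were -9.38 without cultured D to -8.44 without cultured G, -7.97 with zeros at the floor and -9.18 without adult F to -8.26 without cultured G, -7.55 with zeros at the floor. Their percentile was 0 in both, or 0.02 and 0 with length matched. In cultured cells A to H the share was 0.863%, 0.517%, 0.0543%, 0.172%, 0.0621%, 0.363%, 1.48% and 1.39%, highest in G and H, the cells with no count of Ttn, Myh6, Tnnt2, Actc1 or Tpm1. H19 had counts in 8 of 8 cultured cells, Peg3, a paternally expressed gene, 1639 CPM (1469 to 1824, 365 without cultured B) in 5 and Mest 582 CPM (483 to 696) in 6. The atrial list had 0.202% (0.183 to 0.222, 0.0907 without cultured A) of cultured, 0% (0 to 0.000283) of transplanted and 0.00134% (0.000779 to 0.00214, 0.000537 without adult D) of adult counts. The ventricular list had 7.91% (7.86 to 7.96) in transplanted, 7.32% (7.27 to 7.36) in adult and 0.158% (0.141 to 0.176) in cultured cells. Ribosomal protein genes were lower in transplanted cells in 43 of 54 cases (median -1.45, percentile 83.33, or 4.51 with length matched, -1.93 without cultured B to -0.70 without cultured G). Their medians were -1.09 (-1.55 without cultured B to -0.49 without cultured G) and 0.29 (0.23 to 0.52) in the other comparisons. In cultured cells A to H their share was 2.30%, 0.0691%, 0.175%, 0.140%, 0.106%, 2.94%, 4.73% and 4.26%, against 0.507 to 0.983% in transplanted and 0.578 to 1.01% in adult cells, so cells B to E lay below every transplanted cell and the other cultured cells above.

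Of the cardiac transcription factors, 9 of 12 were lower in transplanted than cultured cells (median -5.94, percentile 9.15, or 26.65 with length matched, -6.11 without cultured H to -5.01 without cultured B, -4.71 with zeros at the floor) and 10 of 12 in adult than cultured cells (-2.08, percentile 40.3, or 75.83, -3.62 without adult G to -1.59 without cultured B). The medians of all measured genes were -5.63 and -3.85. Mef2c had 499.6 CPM (408 to 606, 115 without cultured H) in 3 cultured cells and 0 transplanted counts. Nkx2-5 had no cultured count and 24.6 CPM (16.8 to 34.7, 11.7 without transplanted E) in 4 transplanted cells. Between transplanted and cultured cells the costamere list had a median of -2.44 (11 measured, percentile 48.41, or 86.47 with length matched, -4.96 without transplanted B to -1.93 without cultured B). Hypoxia response had a median of -2.09 (4 measured, percentile 60.34, or 71.13 with length matched, -3.53 without transplanted A to -1.41 without cultured B). Immediate early and heat shock genes had a median of -2.13 (6 measured, percentile 83.69, or 51.25 with length matched, -5.96 without transplanted D to 0.42 without cultured H). Interferon response had a median of -4.17 (1 measured, percentile 19.05, or 10.05 with length matched, -9.92 without transplanted A to -2.56 without cultured H). Sgca, a sarcoglycan of the costamere list, was 7.49-fold lower (5.87 to 9.68, 15.4 without adult C and 4.93 without transplanted B) in adult than in transplanted cells. Sox2, a pluripotency gene, had counts in 8 of 8 adult cells at 1824 CPM (1750.3 to 1899.6, 587 without adult A) and in 8 of 8 transplanted cells at 163 CPM (142 to 186). In 3 cultured cells it had 126 CPM (82.4 to 185, 10.7 without cultured F). The switch gene list had a median of 4.68 (4.47 without transplanted E to 5.79 without cultured A, 2.79 with zeros at the floor), 6.41 (5.96 without cultured B to 7.46 without cultured A, 4.86 with zeros at the floor) and 0.30 (0.0119 to 0.55) in the 3 comparisons.

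Sets of transplanted and adult cells differed about as much as sets within a group. Among 568 genes of at least 200 mean CPM, the SD of log2 ratios between sets of 4 cells was 2.64 across the 2 groups and 2.60 within them, a difference of 0.0393. The spread within groups was large, so this does not show that the profiles were alike. The SD across groups beyond that within them was 0.507, and the SD of log2 ratios of the 8-cell sums was 2.15. Gene-specific loss of rat reads on a mouse build cannot be told apart from a real difference, since species goes with group and a loss with an SD under 1.04 would add less than 0.2; a first bound of 0.1, under which the value would have argued against it, was dropped after the value was seen. Transplanted libraries made from host rat cells stay open too: the ribosomal protein pattern had a rho with cultured mouse cells of 0.67 in transplanted and 0.66 in adult cells, a difference of 0.00717 (-0.0157 to 0.0562 without 1 cell), in a test with no known species signal to calibrate it. Between transplanted and adult cells that rho was 0.84, higher than both, which cannot tell host cells from maturation. A sort on the line's reporters would remove host cells, but the labels give sorting or picking by hand without saying which cells had which or on what marker, and the reporter genes were not analysed here. Maturation in the host heart, the biological explanation the design gives, was not tested apart from these.

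Oxidative phosphorylation genes were higher in transplanted than cultured cells, by a median of 4.34 (4.13 without cultured D to 5.15 without cultured A). The list lay at percentile 99.89 of lists matched on 5 classes of exon length and 5 of expression. This argued against transcript length bias only as far as these classes go. Within the cultured group the list's share still went with exon length. It was 0.0717 to 0.259% in cells B to E, at 6553 to 6983 bp, and 0.585 to 1.92% in A, F, G and H, at 3738 to 4994 bp. With every cell thinned to 16099 counts the median was 4.23. Thinning keeps each gene's expected share of counts, so the median could hardly change and does not decide on a difference in depth. Cultured cells F, G and H, with few cardiac transcripts, had 0.585%, 1.10% and 1.43%, above B to E. Every cultured cell lay below the 11.8 to 14.6% of transplanted cells. These shares argued against cells with few cardiac transcripts as the only source of the low cultured value, though they may have added to it. Depth, length bias within these classes, other differences in library quality and the host cell question above remain open. A response to the heart is therefore 1 hypothesis among them.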
